A study of Mus musculus with 19 samples.

How the data were processed

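RNA from the bulbocavernosus (BC) muscle, a perineal muscle that depends on androgen, was sequenced in 19 libraries of male C57BL/6 mice. Control mice carried a floxed androgen receptor gene (Ar) without Cre. mARKO mice carried the same floxed gene and Cre under the human skeletal actin promoter, which removes Ar in muscle fibres. Each genotype had 3 groups: sham surgery, orchiectomy (ORX) followed by vehicle, and ORX followed by TEI-SARM2, a selective androgen receptor modulator (SARM). There were 3 libraries per group, and 4 in the control ORX vehicle group. Per the labels' protocols, dosing began 9 days after ORX and went on for 2 weeks, by mouth, at 10 mg/kg once a week for the SARM. Whether the sham groups received vehicle is not stated. RNA with an integrity number above 8 was used, 1 µg per library, for stranded poly(A) libraries read on a MiSeq. The genotypes were sequenced in separate runs, so a plain difference between genotypes cannot be told apart from a difference between runs. The labels number the replicates without saying that each is a separate mouse, so the p-values measure the spread between these libraries.

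Per the submitters' processing notes, reads were aligned with TopHat to the mouse genome (build mm10), counted per gene with featureCounts and analysed with edgeR, with no versions or settings. Whether the counting used the strand is not stated, so reads of genes that overlap on opposite strands, and of near-identical gene copies, are uncertain in their assignment. The deposited signal values are read counts per gene that the authors divided by 1 size factor per library, separately for each genotype. This was found from the values: within each library 100% of the values are whole multiples of the value of 1 read, within a relative tolerance of 1e-09 (largest deviation 2.76e-10). The deposited p-value and q-value columns hold 1 test per gene and table, and the file headers do not state its contrast. Of 23420 genes per table, the authors' q-value was under 0.05 for 2266 in control and 4473 in mARKO. Of these, 1707 and 4109 were also called here in at least 1 comparison of the same genotype, out of 1968 and 4776 genes so called. The 2 tables list the same genes by symbol, and 27 entries hold a date in place of a symbol, as spreadsheet programs produce. These were kept in the tests and carry no gene name. In the control table, 3 per-library columns matched no sample and were not used.

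The recovered library sizes were 1023757 to 1722492 reads in control and 1205084 to 1827318 in mARKO. The 10 most abundant genes took 16.13% to 23.65% of the reads. Where a group held no read of a gene, a floor of 3 reads over the whole group bounds a fold change. With 1 to 3 reads, ratios have exact 95% intervals. Both cover counting error only. Differences of effects have neither. Amd1 and Amd2 were listed at 0 reads in all 19 libraries and were not tested.

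The plan made before the data were examined was an edgeR quasi-likelihood test on counts, or limma on log values where counts were not given. The values are normalised, so limma was used. Within each genotype, limma-trend (limma 3.58.1, R 4.3.3) was fitted to log2(value + 1) of genes with a mean value of at least 1, with 1 mean per group and a spread shared by the 3 groups. The pseudocount understates the changes of genes with few reads. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Sharing the spread assumes that a group with few libraries varies like the others. For the difference of an effect between genotypes, and for the sham groups of both genotypes, the recovered reads of all 19 libraries were scaled together with TMM (edgeR 4.0.16), and limma was fitted to log2(value + 1) with 6 group means. CPM (reads relative to the library total) were computed from the recovered reads. Unless another tool is named, each adjusted p for a gene is from limma.

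Because whole reads could be recovered, edgeR's quasi-likelihood test was also run on them, a choice made after seeing the data. It called 1655, 1317 and 6 genes in control for ORX vehicle against sham, SARM against vehicle after ORX, and SARM after ORX against sham. In mARKO it called 1272, 2778 and 3656. It called 382 and 618 genes for the ORX and SARM effects that differed between genotypes, and 2076 for the sham groups of both genotypes.

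The Ar level of all libraries was compared between genotypes by an exact two-sided permutation test over 92378 relabelings. In all, 39 gene lists with 834 distinct members, written before the data were examined, were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of 1 comparison. Camera with a correlation estimated for each list, and fry, which tests whether a list's genes move 1 way without comparing them with other genes, were alternatives. Under the estimated correlation, 1 of the 122 list calls held, that of the epithelial markers in the ORX effect that differed between genotypes. Lists with fewer than 5 tested genes have no test: mitochondrially encoded mRNAs (13 members, 0 tested), T, B and NK cell markers (15 members, 2 tested), red blood cell markers (10 members, 4 tested) and male accessory gland markers (15 members, 4 tested). Neutrophil markers (11 members) had 4 tested genes in control, and so no test there, and 6 in mARKO. Counts of called list members are given over all tested genes and adjusted over the list alone.

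Genes are named by a rule fixed before the data were examined. Ar and 13 further genes (Odc1, Amd1, Smox, Fkbp5, Mylk4, Mstn, Igf1, Fbxo32, Trim63, Myh4, Myh1, Myh2 and Myh7) are always named in the comparisons within a genotype and the differences of effects, where tested. Amd1 has 0 reads in every library, and Myh7 is below the filter in mARKO. In each comparison within a genotype and each difference of effects, the 8 called genes with the largest change in each direction are eligible, if their mean CPM was at least 5, they had an official symbol and, within a genotype, no library of 1 group overlapped the other group. Up to 4 members with the smallest p are eligible for each list with a camera adjusted p under 0.05 or at least 3 called members. For the sham groups of both genotypes, Ar and the 5 largest changes in each direction are eligible.

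The scripts were tested on simulated counts drawn from the real means and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold. For ORX vehicle against sham in control, 45% of the 2-fold and 81% of the 4-fold changes were recovered, and 10.6% of the calls were false. For SARM against vehicle after ORX in control these were 37%, 83% and 3.23%, and for SARM after ORX against sham in control 36%, 80% and 7.94%. In mARKO the same comparisons gave 40%, 81% and 4.72%, then 44%, 79% and 7.52%, then 41%, 82% and 6.11%. The ORX effect that differed between genotypes gave 25%, 59% and 11.6%, and the SARM effect that differed gave 20%, 59% and 8.14%.

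The alternatives tried were RLE size factors and total counts in place of the authors' scaling, no filter and a mean CPM of at least 1 or 5, pseudocounts of 0.1 and 5, DESeq2 1.42.0, a fold change of at least 2, an adjusted p under 0.01 or 0.1, only the 2 groups compared, all 19 libraries in 1 fit, the replicate number as a block, and leaving out each library in turn. Added after seeing the data were edgeR on the recovered reads, TMM within the genotype, the level of the epithelial markers as a covariate, and leaving out each library and other pseudocounts for the Ar level and the genes shared by both genotypes. Tables were read with the R package data.table, version 1.17.8. Gene positions are given in mm10.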

Results

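Gene expression in the BC muscle was measured in 19 RNA-seq libraries, 10 from control and 9 from mARKO mice. The groups were control sham (3 libraries), control ORX vehicle (4), control ORX SARM (3), mARKO sham (3), mARKO ORX vehicle (3) and mARKO ORX SARM (3). Library sizes were 1023757 to 1722492 reads in control and 1205084 to 1827318 in mARKO. Group values are means of the authors' normalised reads within a genotype, as mean ± SD over the libraries of the group. Log2 changes are on log2(value + 1), with the standard error (SE) and the limma adjusted p. Scaling to total counts, in place of the authors' size factors, moved the median change of all genes by more than 0.1 in 4 of the comparisons within a genotype. After ORX in control that median was 0.293 with total counts and 0.01 with the authors' scaling, so small shifts of long gene lists are given relative to the other genes by the list test.

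The targeted gene, Ar (X chromosome, 98149750 to 98317147), checks the genotype labels. Control sham libraries held 56 Ar reads over 3 libraries (10 to 28 each), control ORX vehicle 29 over 4 (2 to 14 each) and control ORX SARM 20 over 3 (3 to 9 each). The mARKO libraries held 0 reads after sham, 3 after ORX with vehicle and 9 after ORX with SARM (1 to 4 each). Mean Ar levels were 15.6 ± 5.62, 5.85 ± 4.98 and 4.99 ± 2.82 CPM in the control groups and 0, 0.609 ± 1.05 and 1.79 ± 0.831 CPM in the mARKO groups. Over all libraries, mean log2(CPM + 1) of Ar was 0.643 in 9 mARKO and 2.89 in 10 control libraries, a difference of -2.25 (exact two-sided permutation p = 0.000422). Genotype and sequencing run are the same split, so this difference carries both. Ar counts were low in control too, so a single library says little.

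**Figure D1:**
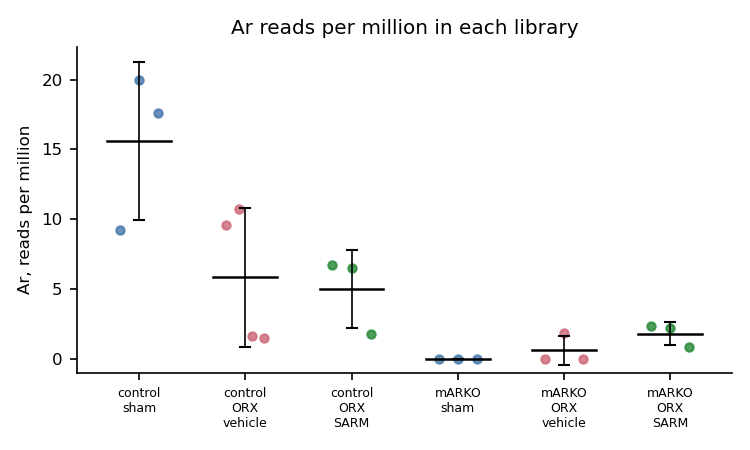
Ar level in CPM in each of the 19 libraries, by group, with lines for the mean ± SD. The 3 mARKO sham libraries are at 0, and the control sham libraries have the highest mean, 15.6 CPM.

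Removal of the testes takes away the main source of testosterone, and the BC muscle shrinks without it. The fibres of this muscle are rich in androgen receptor. The comparison of ORX vehicle with sham in control mice asks which transcripts follow the loss of androgen when the receptor is present. Ar itself was lower after ORX, 7.53 ± 6.7 against 23.7 ± 9.05 normalised reads (log2 -1.90, SE 0.598, adjusted p = 0.0447), a call at the edge of what these counts can show. Of 13475 genes tested, 1661 were called, 658 higher and 1003 lower after ORX, and 726 of them by at least 2-fold. The fast myosin gene Myh1 (chromosome 11, 67200114 to 67224575) fell from 45600 ± 9800 to 3401 ± 956 (log2 -3.78, SE 0.28, adjusted p = 1.02e-07). Mstn, which encodes the growth inhibitor myostatin (chromosome 1, 53061663 to 53068079), fell from 212.1 ± 59.6 to 32.95 ± 12 (log2 -2.67, SE 0.238, adjusted p = 1.03e-06). Fkbp5, a classical androgen and glucocorticoid target, fell from 428 ± 45.7 to 80.14 ± 16.6 (log2 -2.42, SE 0.264, adjusted p = 9.27e-06). The growth factor gene Igf1 fell by 1.87 on the log2 scale, the muscle kinase gene Mylk4 by 1.9 and the polyamine oxidase gene Smox by 1.23. Odc1 (log2 -0.0959, adjusted p = 0.806) and Myh4 (log2 -0.0137, adjusted p = 0.99) were not called. Tfrc, the transferrin receptor gene, fell by 4.62 and the potassium channel gene Kcng4 by 4.74. The cell cycle inhibitor gene Cdkn1a (chromosome 17, 29090986 to 29100722) rose from 13.72 ± 1.95 to 219.5 ± 6.33 (log2 3.91, SE 0.312, adjusted p = 2.28e-07). The haem oxygenase gene Hmox1 rose by 3.30 and the SERCA inhibitor genes Pln by 3.47 and Sln by 2.54. The ubiquitin ligase gene Fbxo32 rose by 1.43 (adjusted p = 0.0072), while Trim63, its usual partner as an atrophy marker, had 0.56 (adjusted p = 0.15). Mup20 fell from 548.6 ± 386 to 1.316 ± 2.1, and reads of such multigene families are uncertain in their assignment. Car6 had 167 reads over the sham libraries and 3 over the vehicle libraries, a ratio of 99.7 (95% interval 33.5 to 488). Without control sham replicate 1, 1109 genes were called. The Ar call ended without any 1 of control sham 1, 2 or 3, vehicle 3 or 4 or SARM 2 (adjusted p 0.0552 to 0.149), and with total counts, no filter, DESeq2 or a pseudocount of 0.1. Myh2 (log2 -0.743, adjusted p = 0.0499) lost its call without sham 2 or 3, vehicle 1, 3 or 4 or SARM 2 (0.0663 to 0.219) and under TMM, RLE and total counts. With total counts 81.3% of the called genes were higher, against 39.6% with the authors' scaling. Myh7 had 13 reads, all in vehicle replicate 3, against 0 in sham, 2.42-fold above the floor, and was not called (adjusted p = 0.522).

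Among gene lists in the same comparison, the cytosolic ribosomal proteins stood out, with 53 of 72 tested genes higher after ORX and 0 lower (62 and 0 adjusted over the list alone, median log2 0.54). Their camera adjusted p was 7.75e-31, and the adjusted p = 0.275 with an estimated correlation. Energy metabolism moved the other way. For oxidative phosphorylation 42 of 66 genes fell (56 adjusted over the list alone, camera adjusted p = 1.57e-25, adjusted p = 0.347 with an estimated correlation). For glycolysis and glycogen 17 of 28 fell (21 and 1 higher adjusted over the list alone, 7.72e-15, adjusted p = 0.275 with an estimated correlation), with Fbp2 down by 2.50. For the TCA cycle 16 of 19 fell (16 and 1 higher adjusted over the list alone, 8.92e-12, adjusted p = 0.275 with an estimated correlation). The fast fibre contractile genes had 9 of 18 lower and 1 higher (11 and 1 adjusted over the list alone, 7.03e-07, adjusted p = 0.377 with an estimated correlation). Muscle atrophy genes had 13 of 26 higher and 1 lower (15 and 2 adjusted over the list alone, 2.35e-07, adjusted p = 0.275 with an estimated correlation). Collagens and other extracellular matrix genes had 13 of 34 lower and 1 higher (15 and 1 adjusted over the list alone, 0.000118, adjusted p = 0.512 with an estimated correlation), with Col3a1 falling from 384.7 ± 81.1 to 80.58 ± 14.9. Of 15 androgen-responsive genes of muscle, 7 fell and 0 rose (7 adjusted over the list alone, 0.000194, adjusted p = 0.23 with an estimated correlation). The epithelial markers, 16 genes of lining tissue, were not called as a list (adjusted p = 0.573, median log2 -0.179). In all, 15 lists were called.

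TEI-SARM2 binds the androgen receptor in place of testosterone. Giving it to castrated control mice asks which of the changes after ORX an androgen receptor ligand brings back. Ar did not differ between ORX SARM and ORX vehicle (log2 0.24, adjusted p = 0.88). In all, 1076 of 13475 genes were called, 691 higher and 385 lower with SARM, and 496 by at least 2-fold. Myh1 rose to 49540 ± 2070 (log2 3.92, SE 0.28, adjusted p = 9.36e-08), above its sham level of 45600 ± 9800. Mstn rose to 130.7 ± 26.2 (log2 2.00, SE 0.238, adjusted p = 3.84e-05) and Mylk4 rose by 1.46 (adjusted p = 5.86e-05). Cdkn1a fell by 2.97, Hmox1 by 3.04, Sln by 3.1 and the glutamine synthetase gene Glul by 1.32. Fkbp5 (log2 0.841, adjusted p = 0.0591), Fbxo32 (-0.973, 0.0788), Myh2 (0.679, 0.0942), Smox (0.424, 0.333), Trim63 (-0.45, 0.297) and Odc1 (-0.431, 0.19) were not called. Nor was Myh7, with 1 read against 13 (ratio 9.29 lower, 95% interval 1.39 to 395, adjusted p = 0.783). Igf1 rose by 1.33 (adjusted p = 0.0184), and Myh4 fell by 1.75 (adjusted p = 0.0487), from 17140 ± 2470 to 8488 ± 9950. Among secreted gland genes Mup20 rose by 7.19, Smr2 by 5.38 and Pip by 4.97, and Ptgds had 324 reads against 3, a ratio of 151 (95% interval 51.3 to 737). The number of calls was 594 without control ORX SARM replicate 2 and 529 without replicate 3. The Igf1 call ended without SARM 2 or 3 (adjusted p 0.0519 and 0.144). The Myh4 call ended without sham 1, 2 or 3, any vehicle library, or SARM 2 or 3 (adjusted p 0.0544 to 0.312), with its log2 change at -0.951 without SARM 3. With total counts 21.3% of the called genes were higher, against 64.2% with the authors' scaling.

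Most of the lists that moved after ORX moved back with SARM. Of the cytosolic ribosomal proteins 31 of 72 fell (59 adjusted over the list alone, camera adjusted p = 1.64e-27, adjusted p = 0.334 with an estimated correlation). Oxidative phosphorylation had 27 of 66 genes higher (39 adjusted over the list alone, 5.13e-20, adjusted p = 0.384 with an estimated correlation), and the TCA cycle 14 of 19 (16 and 1 lower adjusted over the list alone, 8.04e-13, adjusted p = 0.334 with an estimated correlation). Glycolysis and glycogen had 10 higher and 1 lower of 28 (12 and 1 adjusted over the list alone, 4.91e-07, adjusted p = 0.415 with an estimated correlation). Fast fibre contractile genes had 7 higher and 2 lower of 18 (11 and 2 adjusted over the list alone, 4.98e-07, adjusted p = 0.384 with an estimated correlation). Extracellular matrix genes had 13 of 34 higher (19 and 1 lower adjusted over the list alone, 9.1e-09, adjusted p = 0.334 with an estimated correlation). Muscle atrophy genes had 8 of 26 lower (13, with 2 higher, adjusted over the list alone, 3.55e-06, adjusted p = 0.334 with an estimated correlation). The androgen-responsive genes of muscle had 4 higher and 1 lower of 15 (6 and 1 adjusted over the list alone) and were not called (adjusted p = 0.066). In all, 13 lists were called.

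Across the 13475 genes of the control fit, the change with SARM was the mirror of the change after ORX, with a correlation of -0.745 (jackknife SE 0.0936). Genes are not independent replicates. Both changes share the vehicle libraries, which alone gave a mean covariance of -0.0544 in 100 simulations without effects, against -0.287 here. Over 6 splits of them between the changes the correlation was -0.524 (weakest -0.416) and the covariance -0.231 on average. Of the 1661 genes called after ORX, 98.6% changed in the opposite direction with SARM (62.4% in simulations that kept the ORX effect alone). With split vehicle libraries the share was 94.8%. Of the 1661 genes 768 were called in the opposite direction, among them Myh1, Mstn, Cdkn1a and Hmox1, and 1 was called in the same direction. That 768 became 508 without control ORX SARM replicate 2 and 453 without replicate 3. Simulations gave at most 1, but held no SARM effect, so decide nothing.

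Comparing SARM after ORX with sham asks what the treatment left different from intact muscle. In control 12 of 13475 genes were called by limma, 5 higher and 7 lower than in sham, while 1201 had an unadjusted p under 0.05. DESeq2 called 34 genes and edgeR 6. Ar was not called (log2 -1.66, adjusted p = 0.457), nor was Myh1 (log2 0.14, adjusted p = 0.928) or Mstn (log2 -0.672, adjusted p = 0.45). The same held for Igf1 (-0.539, 0.688), Fbxo32 (0.455, 0.739), Trim63 (0.11, 0.933), Mylk4 (-0.444, 0.523), Smox (-0.803, 0.359), Odc1 (-0.527, 0.457), Myh2 (-0.0643, 0.962), Myh4 (-1.76, 0.357) and Myh7 (1 read against 0, adjusted p = 0.929). Tfrc stayed below sham, 98.51 ± 84.3 against 518 ± 60.3 (log2 -2.70, SE 0.35, adjusted p = 0.00605), as did Fkbp5, 159.8 ± 97.4 against 428 ± 45.7 (log2 -1.58, adjusted p = 0.0368). Hpgd, Amot, Phka1, Pptc7 and Ankrd23 were lower by between -0.972 and -1.40 on the log2 scale. Tnfrsf19, Idh2, Gas5 and Mettl7a1 were higher by between 0.908 and 1.36. Glycolysis and glycogen was called as a list with 1 of 28 genes lower (8 adjusted over the list alone, camera adjusted p = 2.94e-11, adjusted p = 0.908 with an estimated correlation). The androgen-responsive genes of muscle had 1 of 15 lower (6 adjusted over the list alone, 2.33e-05, adjusted p = 0.0955 with an estimated correlation). The calls rested on single libraries: 0 genes were called without control sham 2 or without ORX SARM 2, 6 without sham 1, vehicle 1 or SARM 1, and 35 without SARM 3. Without sham 2 and without SARM 2 the adjusted p values were 0.0638 and 0.0699 for Tfrc and 0.257 and 0.254 for Fkbp5, and each of the 11 named genes lost its call without either. Fkbp5 also lost its call without sham 1 or 3, vehicle 1 or SARM 1 (adjusted p 0.0597 to 0.165).

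**Figure D2:**
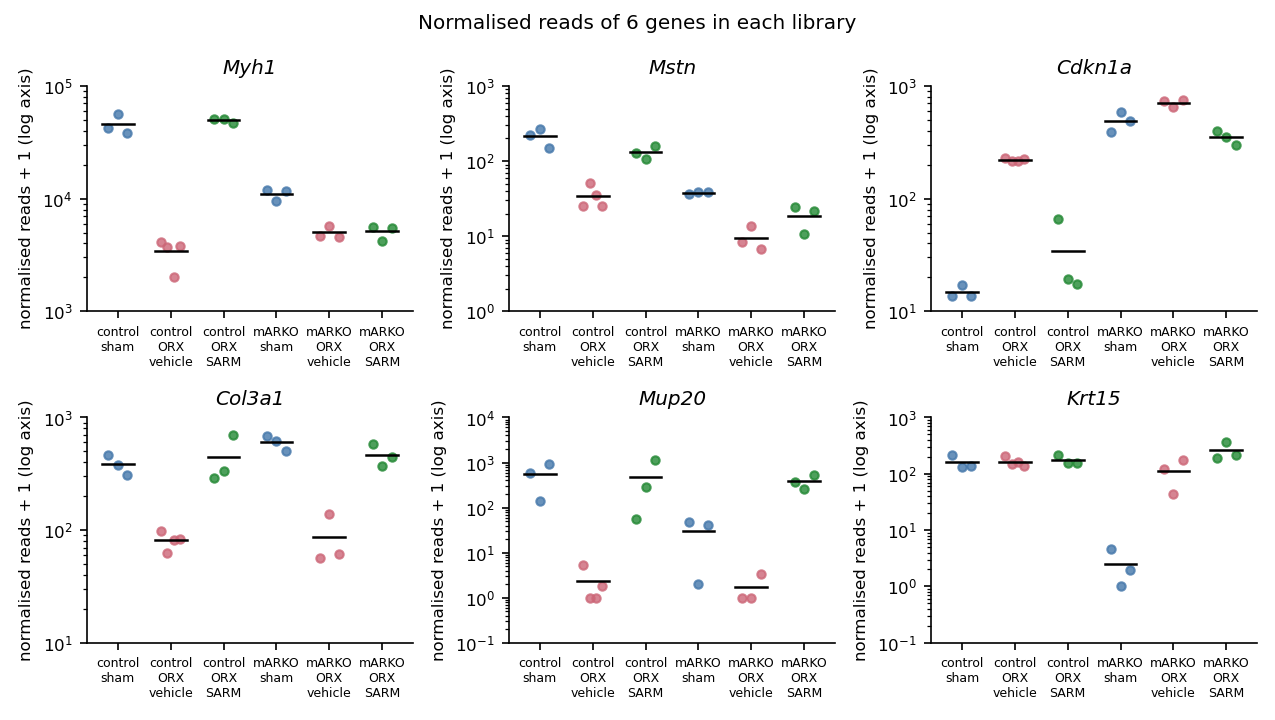
Normalised reads + 1, on a log axis, of Myh1, Mstn, Cdkn1a, Col3a1, Mup20 and Krt15 in each library, with a line at the group mean. Myh1 falls after ORX and returns with SARM in control but not in mARKO, while Col3a1 returns in both. In mARKO the mean of Mup20 is 29.66 in sham, 0.7645 with vehicle and 389.6 with SARM.

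The mARKO mice carry a deletion of the receptor gene aimed at muscle fibres, by a Cre under a muscle actin promoter. ORX in these mice asks which changes still follow castration with that deletion. Ar did not differ (3 reads against 0; log2 0.654, adjusted p = 0.605), and with both groups at or under the floor of 3 reads no fold is given. Of 13755 genes tested, 1320 were called, 585 higher and 735 lower after ORX, and 522 by at least 2-fold. Myh1 fell from 11060 ± 1380 to 5003 ± 662 (log2 -1.14, SE 0.129, adjusted p = 3.35e-05). Mstn fell from 36.77 ± 1 to 8.548 ± 3.57 (log2 -2.05, SE 0.338, adjusted p = 0.000762), Igf1 fell by 2.17 (adjusted p = 0.000446) and Fbxo32 rose by 0.901 (adjusted p = 0.00448). Fkbp5 (log2 -0.579, adjusted p = 0.135), Mylk4 (-0.525, 0.123), Smox (-0.385, 0.502), Trim63 (-0.0695, 0.833), Odc1 (-0.00903, 0.984), Myh2 (0.112, 0.771) and Myh4 (-0.399, 0.155) were not called. The collagen gene Col3a1 fell by 2.92 (chromosome 1, 45311538 to 45349706, from 601.7 ± 91.7 to 85.19 ± 46.8) and Col1a1 by 2.88. The complement gene C7 fell by 4.97 and Tfrc by 2.78. Dcpp3 rose from 10.63 ± 0.0549 to 4498 ± 2310 (log2 8.46, adjusted p = 3.01e-10), and its reads are uncertain against its close copies Dcpp1 and Dcpp2. The keratin gene Krt15 (chromosome 11, 100131759 to 100135949) rose from 1.509 ± 1.84 to 112.8 ± 66.3 (log2 5.56, SE 0.485, adjusted p = 1.76e-06). Krt4 had 175 reads over the vehicle libraries against 1 in sham, a ratio of 173 (95% interval 30.6 to 6860), and Dmbt1 325 against 1, a ratio of 321 (57.2 to 12700). The mean log2(CPM + 1) of the epithelial markers was 0.988 ± 0.483 in mARKO sham, 3.78 ± 1.02 in ORX vehicle and 5.37 ± 0.201 in ORX SARM, against 4.44 ± 0.24, 4.49 ± 0.288 and 4.51 ± 0.131 in the control groups. With that level as a covariate, 106 genes were called. With total counts 66.7% of the called genes were higher, against 44.3% with the authors' scaling.

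Among the lists, 71 of 74 cytosolic ribosomal proteins rose and 0 fell (71 adjusted over the list alone, median log2 0.64, camera adjusted p = 2.81e-67, adjusted p = 0.0621 with an estimated correlation). Oxidative phosphorylation had 38 of 66 lower (49 adjusted over the list alone, 1.29e-27, adjusted p = 0.0823 with an estimated correlation). Glycolysis and glycogen had 17 of 28 lower (20 and 1 higher adjusted over the list alone, 1.12e-12, adjusted p = 0.168 with an estimated correlation). The TCA cycle had 16 lower and 1 higher of 19 (17 and 1 adjusted over the list alone, 2.59e-12, adjusted p = 0.124 with an estimated correlation). Extracellular matrix genes had 24 of 35 lower (26 adjusted over the list alone, median log2 -1.37, 4.18e-26, adjusted p = 0.0823 with an estimated correlation). Pericyte and smooth muscle markers had 12 of 15 lower (12 adjusted over the list alone, 9.4e-12, adjusted p = 0.0621 with an estimated correlation). Epithelial markers had 13 of 16 higher (14 adjusted over the list alone, median log2 3.45, 3.99e-17, adjusted p = 0.124 with an estimated correlation). Muscle atrophy genes had 9 of 26 higher (17 and 1 lower adjusted over the list alone, 3.1e-07, adjusted p = 0.124 with an estimated correlation). Fast fibre contractile genes had 7 lower and 1 higher of 18 (10 and 1 adjusted over the list alone, 2.38e-06, adjusted p = 0.203 with an estimated correlation). The androgen-responsive genes of muscle had 2 higher and 2 lower of 15 (2 and 7 adjusted over the list alone) and were not called (adjusted p = 0.249). In all, 21 lists were called.

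SARM given to castrated mARKO mice meets a receptor deleted, by design, in the fibres, though the reads do not show where any remaining Ar lies. The comparison with vehicle asks what the compound still changes in the whole muscle. Ar had 9 reads against 3 (ratio 2.73, 95% interval 0.681 to 15.7; log2 1.17, adjusted p = 0.213) and was not called. Of 13755 genes, 2719 were called, 1739 higher and 980 lower, and 1272 by at least 2-fold. Myh1 did not respond, 5123 ± 766 against 5003 ± 662 (log2 0.0309, SE 0.129, adjusted p = 0.897). Myh2 fell from 6021 ± 831 to 2557 ± 599 (log2 -1.25, SE 0.172, adjusted p = 0.000104). Trim63 fell by 0.663 (adjusted p = 0.00324) and Fbxo32 by 0.719 (adjusted p = 0.011), while Mstn (log2 0.954, adjusted p = 0.0573), Fkbp5 (-0.115, 0.769), Mylk4 (-0.283, 0.357), Smox (0.144, 0.779), Odc1 (-0.173, 0.491) and Myh4 (-0.32, 0.19) were not called. Igf1 rose by 1.28 (adjusted p = 0.012). The acetylcholine receptor gene Chrna1 fell from 105.4 ± 22.8 to 45.51 ± 6.71 (log2 -1.18, SE 0.197, adjusted p = 0.00048), Chrnb1 by 0.981, and the myogenic factor genes Myog by 1.32 and Myod1 by 1.36. Xirp1, Serpine1 and Gdf5 fell by between 2.08 and 2.16, and Pdk4 by 1.91. Smr2 went from 22.72 ± 26.3 to 1851 ± 392 (log2 6.94) and Mup20 had 1159 reads against 2, a ratio of 527 (95% interval 146 to 4360). The amino acid synthesis genes Asns and Phgdh rose by 3.18 and 2.66, and Col1a1 by 2.55. With the epithelial marker level as a covariate, 351 genes were called. The Fbxo32 call ended without vehicle 1 or SARM 3 (adjusted p 0.0579 and 0.06) and with DESeq2, and the Igf1 call without SARM 3 (0.0653).

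Muscle atrophy genes had 13 of 26 lower with SARM (16 and 1 higher adjusted over the list alone, median log2 -0.64, camera adjusted p = 3.82e-09, adjusted p = 0.147 with an estimated correlation). Denervation and neuromuscular junction genes had 9 of 20 lower (10 adjusted over the list alone, 1.08e-05, adjusted p = 0.146 with an estimated correlation). Extracellular matrix genes had 24 higher and 1 lower of 35 (25 and 1 adjusted over the list alone, median log2 1.12, 7.6e-12, adjusted p = 0.253 with an estimated correlation). Macrophage and dendritic cell markers had 12 of 20 higher (15 adjusted over the list alone, 3e-06, adjusted p = 0.253 with an estimated correlation). Epithelial markers had 7 of 16 higher (11 adjusted over the list alone, 0.000166, adjusted p = 0.345 with an estimated correlation). The ribosomal proteins had 19 lower and 2 higher of 74 (32 and 2 adjusted over the list alone, median log2 -0.216, 6.96e-10, adjusted p = 0.305 with an estimated correlation). Oxidative phosphorylation had 7 of 66 lower (2 adjusted over the list alone, 4.21e-06, adjusted p = 0.305 with an estimated correlation). Glycolysis and glycogen had 10 of 28 lower (14 adjusted over the list alone, 1.08e-05, adjusted p = 0.305 with an estimated correlation). The TCA cycle had 5 of 19 lower (6 adjusted over the list alone, 0.000151, adjusted p = 0.305 with an estimated correlation). Fast fibre contractile genes had 6 lower and 1 higher of 18 (7 and 2 adjusted over the list alone, 0.000411, adjusted p = 0.322 with an estimated correlation). The androgen-responsive genes of muscle were not called (adjusted p = 0.853). In all, 22 lists were called.

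Across 13755 genes in mARKO the SARM and ORX changes had a correlation of -0.00292 (jackknife SE 0.158). The covariance was -0.00141 (mean -0.0653 in simulations without effects). Of the 1320 genes called after ORX, 57.6% changed in the opposite direction with SARM (65.2% in simulations that kept the ORX effect alone). Of these, 317 were called in the opposite direction, among them Col3a1 and Col1a1, and 206 in the same direction. Simulations gave at most 2, but held no SARM effect, so decide nothing. The 317 became 205 without mARKO ORX vehicle replicate 1, and with 1 library left out the correlation lay between -0.158 (without vehicle 3) and 0.0373 (without sham 1). It was also positive without sham 3 (0.0197) and SARM 1 (0.00621).

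**Figure D3:**
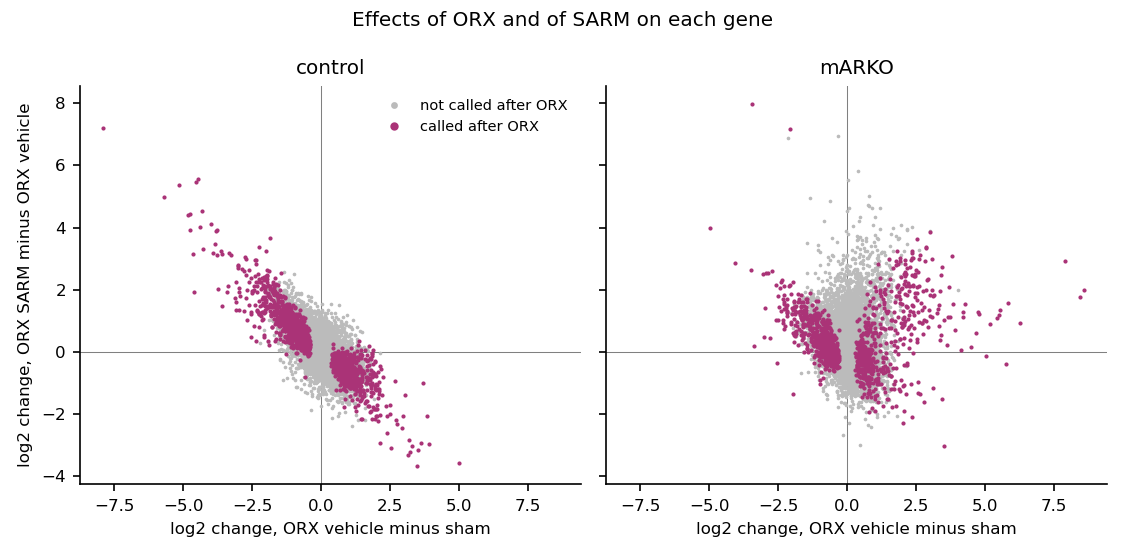
Log2 change with SARM after ORX against log2 change after ORX, 1 point per gene, in control and in mARKO, with genes called after ORX coloured. In control 98.6% of the coloured genes lie on opposite sides of 0 on the axes, in mARKO 57.6%. In mARKO the epithelial markers rose in both steps, with medians of 3.45 and 1.27.

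The distance of SARM-treated mARKO muscle from mARKO sham asks whether the treatment returned the tissue to its intact state. It did not by count: 3859 of 13755 genes were called, 2208 higher and 1651 lower, and 1677 by at least 2-fold. Ar had 9 reads against 0, 2.70-fold above the floor (log2 1.82, adjusted p = 0.0389). The reads do not show in which tissue they lie. Myh1 (log2 -1.11, adjusted p = 8.15e-06), Myh2 (-1.14, 9.28e-05) and Myh4 (-0.718, 0.00315) were lower. Mylk4 (-0.809, 0.00573), Trim63 (-0.733, 0.000882), Mstn (-1.09, 0.0221) and Fkbp5 (-0.694, 0.0305) were lower too, while Igf1 (-0.895, 0.0569), Fbxo32 (0.182, 0.519), Smox (-0.242, 0.598) and Odc1 (-0.182, 0.442) were not called. The Mstn call ended without sham 1, 2 or 3 or SARM 2 (adjusted p 0.0534 to 0.129) and with DESeq2, and that of Fkbp5 without sham 1, 2 or 3 or SARM 3 (0.0595 to 0.14) and with total counts. The tyrosine hydroxylase gene Th had -3.31, the embryonic myosin gene Myh3 -3.19 and Tfrc -2.34. Krt15 was higher by 6.91, Bhlha15 by 6.88 and Dcpp2 by 10.8, and Dcpp1 had 11117 reads against 3, a ratio of 3330 (95% interval 1140 to 16100). The class I genes H2-K1 and B2m, of a family with near-identical members in the case of H2-K1, were higher by 3.23 and 2.83. Fast fibre contractile genes had 17 of 18 lower (17 adjusted over the list alone, camera adjusted p = 2.29e-10, adjusted p = 0.11 with an estimated correlation). Oxidative phosphorylation had 61 of 66 lower (63 adjusted over the list alone, 2.3e-27, adjusted p = 0.11 with an estimated correlation) and glycolysis and glycogen 27 of 28 (27 adjusted over the list alone, 6.25e-17, adjusted p = 0.11 with an estimated correlation). The TCA cycle had 17 of 19 lower (17 and 1 higher adjusted over the list alone, 8.47e-13, adjusted p = 0.11 with an estimated correlation). Ribosomal proteins had 61 of 74 higher (67 adjusted over the list alone, 2.19e-19, adjusted p = 0.124 with an estimated correlation). Epithelial markers had 14 of 16 higher (14 adjusted over the list alone, median log2 5.20, 1.72e-13, adjusted p = 0.11 with an estimated correlation). Macrophage and dendritic cell markers had 15 of 20 higher (16 adjusted over the list alone, 2.27e-06, adjusted p = 0.11 with an estimated correlation). Muscle atrophy genes were not called (adjusted p = 0.177), nor were the androgen-responsive genes of muscle (adjusted p = 0.388). In all, 19 lists were called. With the epithelial marker level as a covariate 8 genes were called, but this level follows the groups and cannot separate tissue share from treatment. The Ar call ended without sham 1, 2 or 3 or SARM 1 or 2 (adjusted p 0.0778 to 0.123) and with DESeq2, and with total counts 76.3% of the called genes were higher, against 57.2%.

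**Figure D4:**
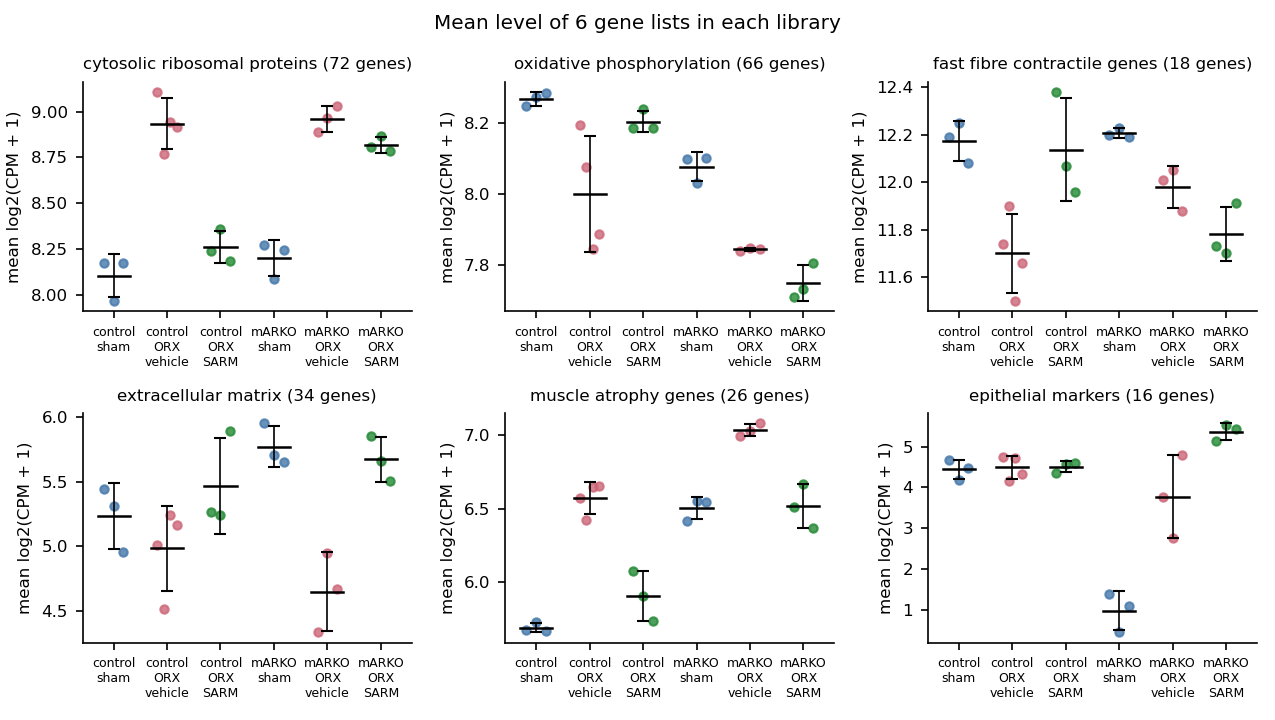
Mean log2(CPM + 1) per library of 6 gene lists, by group, with bars for the mean ± SD. The epithelial markers lie at 0.988 in mARKO sham and near 4.44 to 4.51 in the control groups.

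Whether an effect differs between genotypes was tested directly, since a gene called in 1 genotype alone does not show it. Each effect is a difference within 1 sequencing run. For ORX, 413 of 13601 genes differed, 246 with a more positive change in mARKO and 167 with a more negative one. Ar was not among them (log2 2.50, adjusted p = 0.149). The fall of Myh1 was smaller in mARKO by 2.60 on the log2 scale (SE 0.306, adjusted p = 8.99e-06) and that of Fkbp5 by 1.81 (SE 0.399, adjusted p = 0.0125). Mylk4 differed by 1.34 (adjusted p = 0.0143) and Fbp2 by 2.06 (adjusted p = 1.58e-06). Cdkn1a rose less in mARKO (-3.39, SE 0.39, adjusted p = 7.79e-06), where it was already at 485.8 ± 98.8 in sham. Sln had -2.37 and the signalling gene Pik3r1, which rose in control and fell in mARKO, -2.21. For Mstn (0.609, 0.53), Igf1 (-0.323, 0.842), Fbxo32 (-0.562, 0.61), Smox (0.81, 0.363), Trim63 (-0.664, 0.326), Myh2 (0.82, 0.24), Myh4 (-0.42, 0.838) and Odc1 (0.0522, 0.96) no difference was called. Krt15 differed by 5.38 and Dcpp2 by 10.6. The epithelial markers, with 9 of 16 genes more positive in mARKO (14 adjusted over the list alone), had a camera adjusted p of 2.73e-23, and an adjusted p = 0.0333 with an estimated correlation. The androgen-responsive genes of muscle had 4 of 15 more positive (4 adjusted over the list alone, 0.00242, adjusted p = 0.0503 with an estimated correlation). Extracellular matrix genes had 0 of 34 called (4 more negative adjusted over the list alone, 7.04e-09, adjusted p = 0.333 with an estimated correlation). In all, 17 lists were called. The 413 genes became 260 without control sham 3, 203 and 265 without mARKO sham 2 and 3, and 243 and 238 without mARKO vehicle 1 and 3, and the Mylk4 call ended without mARKO vehicle 1 (adjusted p = 0.0567). With the epithelial marker level as a covariate 25 genes were called, and with total counts 35.8% of the calls were more positive, against 59.6%.

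For SARM after ORX, 497 of 13601 genes differed between genotypes, 120 with a more positive change in mARKO and 377 with a more negative one. Ar was not among them (log2 0.836, adjusted p = 0.695). The rise of Myh1 in control had no counterpart in mARKO (-3.89, SE 0.306, adjusted p = 2.61e-08). The mitochondrial creatine kinase gene Ckmt2 had -3.19 (SE 0.203, adjusted p = 5.43e-10), going from 173 ± 34.3 to 1085 ± 208 in control and from 250 ± 20.8 to 172.5 ± 22 in mARKO. Mylk4 had -1.75 (adjusted p = 0.00111), Myh2 -1.94 (adjusted p = 0.00158) and Fbp2 -2.13 (adjusted p = 1.42e-06). Differences in the other direction included Hnf1b (3.22), Gyltl1b (3.06) and Hopx (2.77). For Mstn (-1.07, 0.179), Igf1 (-0.0716, 0.966), Fkbp5 (-0.965, 0.204), Fbxo32 (0.246, 0.837), Trim63 (-0.221, 0.788), Smox (-0.29, 0.784), Odc1 (0.251, 0.703) and Myh4 (1.42, 0.271) no difference was called. Energy and contractile lists differed by camera, but none with an estimated correlation. With SARM the epithelial marker level rose from 3.78 to 5.37 in mARKO and from 4.49 to 4.51 in control. Dilution of muscle RNA was not tested for these lists. Oxidative phosphorylation had 28 of 66 genes more negative in mARKO (51 adjusted over the list alone, camera adjusted p = 8.74e-38, adjusted p = 0.163 with an estimated correlation). In the same order, the TCA cycle had 14 of 19 (18, 3.67e-24, 0.0539). Glycolysis and glycogen had 13 of 28 (18, 1.43e-18, 0.163), and fast fibre contractile genes 9 of 18 (13, 1.16e-14, 0.163). Muscle atrophy genes (adjusted p = 0.491) and extracellular matrix genes (adjusted p = 0.302) were not called. In all, 11 lists were called. The 497 genes became 310 and 290 without mARKO vehicle 1 and 2, 315 without mARKO SARM 1 and 776 without control vehicle 2. With total counts 76.1% of the calls were more positive, against 24.1%, and with the epithelial marker level as a covariate 46 genes were called.

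Genes that move in both genotypes are of interest for responses that the deletion leaves in place. Of 13255 genes tested in both, 184 rose after ORX in control and in mARKO, where independent lists would share 28.8 (exact hypergeometric p = 8.93e-103), and 318 fell in both, against 54 (p = 6.54e-178). Genes are not independent, so these p-values describe the lists. Mstn, Igf1, Tfrc, C7 and the collagen genes Col3a1 and Col1a1 fell in both genotypes, and Fbxo32, Bnip3 and Glul rose in both. With SARM 284 genes rose in both, against 88.6 for independent lists, among them Col3a1, Smr2 and Pip. In all, 175 fell in both, against 28.2, among them Cdkn1a, Bnip3, Glul and Sln. Of the genes that rose with SARM in control 43 fell in mARKO, and of those that fell 2 rose. Compared with sham, SARM-treated muscle shared 3 higher and 6 lower genes, Tfrc and Phka1 among the lower ones, and both lost their control call without control sham 2 or SARM 2 (adjusted p 0.0638 to 0.175). The 284 became 186 and 188 without control vehicle 1 and 2 and 114 and 102 without control SARM 2 and 3. The 175 became 109 and 108 without control SARM 2 and 3. The 3 and 6 became 0 and 0 without control sham 2 and without control SARM 2, 6 and 12 without SARM 3, 1 and 3 without SARM 1, and 1 and 2 without vehicle 1, and the 6 became 1 without sham 1.

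Muscle with the deletion can differ from control muscle without castration. The sham groups of both genotypes were compared for this, with genotype and sequencing run as the same split. Ar had 0 reads over the mARKO and 56 over the control sham libraries, 25.8-fold above the floor (log2 -4.60, adjusted p = 1.85e-05). Of 13601 genes, 2327 were called, 1138 higher and 1189 lower in mARKO, and 1302 by at least 2-fold. The mean epithelial marker level was 0.988 ± 0.483 in mARKO sham and 4.44 ± 0.24 in control sham, and with that level as a covariate 68 genes were called. The matrix gene Cilp was higher by 5.29 and the myosin-binding gene Mybph by 5.13 on the log2 scale. Diras2 had 161 reads in mARKO sham and 0 in control sham, 38.8-fold above the floor, and Nxph4 118 and 0, 28.5-fold above it. The embryonic myosin gene Myh3 had 323 and 2, a ratio of 117 (95% interval 32.1 to 969). Krt15 was lower by 6.35 on the log2 scale, Dcpp2 by 9.62 and Dcpp3 by 8.99. Dcpp1 had 3234 reads in control sham and 3 in mARKO sham, a ratio of 1490 (95% interval 509 to 7230), and Dmbt1 181 and 1, a ratio of 250 (44.3 to 9930). All 11 genes named here kept their calls when any library was left out.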

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

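The tests of the epithelial and secreted gene patterns and of dilution of muscle RNA, and the count of splits that mix the labels of both genotypes, were chosen only after the result was seen. So were the scaling tests of the atrophy and ribosomal protein genes, because their planned form, a median relative to all genes, cannot move with the scaling and decides nothing. The counts over other splits of the libraries and the gene length test were planned. The intervals of median changes below come from 2000 bootstrap draws over the genes, with the libraries kept fixed. Genes of a list are not independent, and these intervals do not cover the spread between libraries. What they argue against holds for these libraries only.

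The effect of ORX differed between the genotypes in 413 genes and that of SARM after ORX in 497, by the test of the difference itself. For ORX the genes with a larger value in mARKO included Fkbp5 1.81 (adjusted p = 0.0125), Mylk4 1.34 (0.0143), Myh1 2.60 (8.99e-06), Dcpp2 10.6 (2.19e-09), Dcpp1 10.3 (3.15e-08), Dcpp3 9.97 (4.54e-10), Dmbt1 8.09 (1.03e-05), Ltf 6.65 (0.000259), Pip 5.67 (0.0176), Krt15 5.38 (1.58e-06) and Psca 5.23 (1.09e-05). Those with a smaller value included Stc2 -4.55 (9.81e-05), Pln -3.83 (0.00413), Kcnmb1 -3.72 (0.0477), Itga8 -3.55 (0.0258), Myh3 -3.50 (0.0495), Cdkn1a -3.39 (7.79e-06), Tdh -3.21 (0.00218) and Tnfrsf23 -2.72 (0.00425). For SARM the larger values in mARKO included Scgb2b27 3.46 (0.0496), Hnf1b 3.22 (0.00852), Pln 3.11 (0.0172), Gyltl1b 3.06 (0.0108), Blnk 2.98 (0.0364), Hopx 2.77 (4.85e-05), Dkk3 2.62 (0.0236) and Pyroxd2 2.55 (0.0466). The smaller ones included Myh1 -3.89 (2.61e-08), Slc30a2 -3.36 (7.7e-05), Cdhr3 -3.31 (7.94e-05), Cacna1e -3.24 (0.0212), Ckmt2 -3.19 (5.43e-10), Vgll2 -3.17 (0.00554), Serpine1 -3.13 (0.000966), Kcng4 -2.93 (0.000881), Myh2 -1.94 (0.00158) and Mylk4 -1.75 (0.00111). Psca had 0 reads in all mARKO sham libraries and Stc2 0 in all control sham libraries, so these fitted values depend on the pseudocount. Calls near the threshold ended without single libraries: Kcnmb1 (adjusted p 0.0505 to 0.146), Myh3 (0.0543 to 0.168), Itga8 (0.0503 to 0.0704), Pip (0.0514 to 0.0584), Blnk (0.0598 to 0.125), Dkk3 (0.0589 to 0.0756), Pyroxd2 (0.0522 to 0.161), Scgb2b27 (0.05 to 0.173), Cacna1e (0.0502 to 0.061), Pln for SARM (0.0654 without mARKO SARM 3) and Mylk4 for ORX (0.0567 without mARKO vehicle 1). Reads of the Dcpp and Scgb families are uncertain in their assignment.

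Among the 4 control ORX vehicle libraries, 3 of 34 genes tested had 1 library far from the others: Myh7 at 12.01 in replicate 3 (the others 0), Scgb1b27 at 178.6 in replicate 4 (69.47 to 82.41) and Scgb2b27 at 126.5 in replicate 4 (61.75 to 69.27). Chance gives about 1 in 20.

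Other splits of the same libraries were counted for each number of called genes. After ORX in control only the real split, 1 of 35, called as many as 1661 genes (the next had 456), and for SARM in control 1 of 35 called 1076 (the next 183). For the ORX difference between genotypes 2 of 100 splits called 413 or more, the other being 791 with every control label and 33.3% of the mARKO labels kept. For the SARM difference it was 5 of 100 for 497, the larger ones calling 2369 (66.7% of the control and 0% of the mARKO labels kept), 1611 (33.3% and 100%), 1268 (33.3% and 0%) and 565 (100% and 33.3%). By the rule set beforehand, 5 of 100 leaves chance open for the SARM difference. Each of these larger splits keeps or exchanges all labels of 1 genotype and so carries its labelled effect. Shuffled labels stand for no effect in either genotype, not for equal effects in both, so neither count decides on the difference. Of the splits that mix the labels of both genotypes, 0 of 88 for ORX and 0 of 75 for SARM called as many genes as the real labels, with at most 2 and 0 genes called. Mixing puts the treatment effects into the spread within groups, so few calls follow whether or not the effects differ. These counts decide nothing either. The other comparisons have 10 splits, too few to decide: 2 reached 12 genes for SARM against sham in control (the other 15), and 1, the real one, reached 1320, 2719 and 3859 in mARKO and 2327 between sham groups, with 0 called in every other split.

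The first pattern weighed is the rise of epithelial and gland genes across the mARKO groups, from 0.988 in sham to 3.78 after ORX and 5.37 with SARM, with control at 4.44 to 4.51. Depth or scaling is argued against by a median log2 change from sham to SARM of at least 5.16 with every scaling. A direct androgen response in a constant share of epithelial cells needs a fall after ORX. It is argued against by a median of 3.45 (95% interval over genes 2.01 to 4.13). The mean level was 2.756 to 4.803 in the mARKO vehicle libraries and 0.4567 to 1.401 in the mARKO sham libraries. A different share of epithelial and gland tissue in the sampled muscle cannot be told apart from the groups: within groups, gland genes outside the list correlated with the markers at 0.708 (permutation p = 0.0157), and at 0.498 (permutation p = 0.0951) without mARKO ORX vehicle replicates 2 and 3. For the secreted gland proteins after ORX in control, with a median of -4.99, a lower share of epithelial tissue is not seen in the epithelial markers, at -0.179 (interval -0.503 to 0.096), but the gland genes were lower too, at -1.87 (interval -2.79 to -1.57), so a lower share of gland tissue cannot be told apart. The 6 secreted protein genes (Mup20, Mup4, Smr2, Pip, Car6 and Ptgds) and the 7 gland genes (Dcpp1, Dcpp2, Dcpp3, Dmbt1, Prol1, Ltf and Bhlha15) were picked after their values were seen. Under SARM in mARKO the secreted proteins lay 5.63 above the epithelial markers (interval 3.74 to 6.31), which for genes picked in this way does not decide on a response to androgen in gland cells that keep Ar.

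The second pattern is the lower level of atrophy and denervation genes with SARM in mARKO, a median of -0.623 over 45 genes. Neither list holds its call with an estimated correlation (adjusted p 0.147 and 0.146). Dilution of muscle RNA by other tissue is argued against as the whole cause in these libraries. The median lay -0.365 below that of the fast fibre contractile genes (interval over genes -0.492 to -0.0677). The spread between libraries was not part of this test. Depth or scaling is argued against, with a median of at most -0.577 over the 4 scalings (interval -0.678 to -0.291). A response to the compound that the deletion leaves in place may stay as a hypothesis, and a different muscle composition between animals was not tested.

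The third pattern is the rise of ribosomal protein genes after ORX in both genotypes. Gene length is argued against: the upper limit for random lists matched on exonic length and level was 0.139, against medians of 0.54 in control and 0.64 in mARKO. A few genes taking most of the reads is argued against by a median of at least 0.535 with every scaling (interval 0.483 to 0.597). A higher share of ribosomal protein transcripts after loss of androgen may remain as a hypothesis. The list does not hold its call with an estimated correlation (adjusted p 0.275 and 0.0621).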

How the results depend on the processing

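The epithelial marker covariate and the split of vehicle libraries were chosen only after the result was seen. Causes named below as not tested were not tested. With a fold change of at least 2, the counts were 726, 496, 522, 1272 and 1677 (control ORX, control SARM, mARKO ORX, SARM, SARM against sham), 284 for the SARM difference and 1302 between sham groups, and with adjusted p under 0.01 they were 792, 482, 3, 669, 1540, 2542, 136, 196 and 1312, stricter thresholds keeping fewer genes. Total counts gave 2712, 1807 and 965 (control ORX, control SARM, SARM difference), DESeq2 812 and 1742 (mARKO ORX and SARM), and the cause was not tested. For SARM against sham in control, DESeq2 gave 34, edgeR 6, only the 2 groups compared 3, all 19 libraries in one fit 32 and a pseudocount of 0.1 gave 7. With the epithelial marker level as a covariate, 106, 351, 8, 25, 46 and 68 genes were called (mARKO ORX, SARM, SARM against sham, ORX difference, SARM difference, sham groups). This level follows the mARKO groups, so the covariate takes part of each effect. Of the list calls, 0 held with an estimated correlation in 7 comparisons and 1 in the ORX difference, and fry called 0 (control SARM against sham), 4 and 5 (ORX and SARM differences). The covariate left 13, 9 and 8 (mARKO ORX, mARKO SARM against sham, ORX difference) and turned 9 lists, with adjusted p: interferon 0.677 and unfolded protein 0.111 in mARKO ORX, epithelial 0.776 in mARKO SARM, matrix 0.398, integrated stress 0.828 and proteasome 0.628 in mARKO SARM against sham, integrated stress 0.626 and unfolded protein 0.641 in the ORX difference, and epithelial 0.303 in the SARM difference.

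The reversal in control was -0.524 and 94.8% with vehicle libraries split, which removes the shared libraries. In mARKO the correlation was 0.0896 with mean CPM of at least 5 and 0.0115 with a pseudocount of 5. Genes shared by genotypes with SARM were 464 higher and 289 lower at adjusted p under 0.1. Against sham they were 6 higher at adjusted p under 0.1, 43 and 97 at unadjusted p under 0.01, and 2 lower with a pseudocount of 0.1.

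Leaving out 1 library gave 1109 to 1791, 529 to 1124 and 0 to 35 genes (control ORX, SARM, SARM against sham), 899 to 1298, 1951 to 2972 and 3104 to 4054 in mARKO, 203 to 493 and 290 to 776 for the differences and 1689 to 2442 between sham groups. Called lists were 14 to 16, 12 to 15 and 4 to 8 in control, 16 to 22, 20 to 23 and 18 to 21 in mARKO, and 14 to 19 and 9 to 14 for the differences. The reversal was -0.76 to -0.671, 96.6 to 99.2% and 453 to 760 genes in control, and -0.158 to 0.0373, 54.9 to 66.6% and 205 to 348 in mARKO. Shared genes were 142 to 187 higher and 224 to 338 lower for ORX, 102 to 401 and 108 to 188 for SARM, and 0 to 6 and 0 to 12 against sham. Ar was -2.43 to -2.08 between genotypes.

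Some genes not called became called. With total counts these were Trim63 after ORX in control (0.866, adjusted p 0.0157), Odc1 (-0.689, 0.035) and Fbxo32 (-1.23, 0.0158) with SARM in control, and Mstn with SARM in mARKO (0.999, 0.0443). With SARM in control Fkbp5 was called by DESeq2 (0.993, 0.0124) and edgeR (1.01, 0.0266), and Fbxo32 (-0.984, 0.0376) and Myh2 (0.647, 0.0166) with the replicate block. With 1 library left out, 15 of 264 values became calls. In control these were Trim63 after ORX (without SARM 1 or 3) and with SARM (SARM 1), and with SARM Odc1 (vehicle 2), Fkbp5 (vehicle 2, SARM 2), Myh2 (vehicle 2, SARM 1) and Fbxo32 (SARM 1). In mARKO they were Fkbp5 (vehicle 3) and Mylk4 (SARM 3) after ORX, and with SARM Mstn (vehicle 2, SARM 2), Myh4 (vehicle 3) and Mylk4 (SARM 3). These counts cover ORX and SARM after ORX within a genotype. Genes not called changed sign as follows: Odc1 after ORX in control 0.209 (total counts) and -0.243 to 0.0727 with 1 library left out, and in mARKO 0.0066 (RLE), 0.121 (total counts) and -0.15 to 0.21. Myh4 after ORX in control had 0.294 (total counts), 0.0286 (TMM) and -0.205 to 0.274 without a library. Ar with SARM in control had -0.0473 (DESeq2), -0.0618 (edgeR), -0.166 (replicate block) and -0.166 to 0.786. Trim63 after ORX in mARKO had 0.0617 (total counts) and -0.251 to 0.0342. Myh1 with SARM in mARKO had -0.0166 (TMM) and -0.0394 to 0.162. Without a library, Myh7 with SARM in control had -0.925 to 0.403, and in mARKO Myh2 after ORX -0.0951 to 0.271, Smox -0.612 to 0.0527 after ORX and -0.294 to 0.37 with SARM, and Fkbp5 with SARM -0.432 to 0.219.

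Of 655 calls of named genes none turned, and 3 were lost with RLE, 39 with total counts, 24 without a filter, 17 with the replicate block, 44 with a pseudocount of 0.1 and 2 with 5. TMM lost 3 of 552, DESeq2 51 of 642, edgeR 15 of 645 and a left-out library 589 of 7122. Of 122 list calls fry lost 39, total counts 10, TMM 1 of 94, no filter 3, the replicate block 3 and a pseudocount of 0.1 gave 4 lost. Correlations of libraries with the same replicate number were -0.174 to 0.293 over 18 pairs, and 8 of 19 libraries correlated best with their own number. At this depth, of 100 genes changed by 2 times in simulated data, 36 to 45 were recovered in comparisons within a genotype, and 20 and 25 for the differences.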

Other observations

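Stress, signalling and lipid gene lists also moved, and none of their calls held with an estimated correlation. The parenthesis after a count opens with that count adjusted over the list alone, in the same order. Immediate early genes rose after ORX, 7 of 20 in control (8 and 1 lower, camera adjusted p = 0.000484, adjusted p = 0.275 with an estimated correlation) and 11 of 20 in mARKO (12, 2.66e-07, adjusted p = 0.172 with an estimated correlation). With SARM 1 of 20 fell in control (4, 0.00158, adjusted p = 0.334 with an estimated correlation), and 3 fell and 1 rose in mARKO (4 and 2, 0.0198, adjusted p = 0.413 with an estimated correlation). Glucocorticoid-responsive genes had 7 higher and 2 lower of 15 after ORX in control (7 and 2, 0.0144, adjusted p = 0.324 with an estimated correlation) and 5 higher in mARKO (8 and 1 lower, 0.00174, adjusted p = 0.387 with an estimated correlation). With SARM 3 fell in control (5 and 2 higher, 0.0143, adjusted p = 0.334 with an estimated correlation), and 8 fell and 1 rose in mARKO (10 and 1, 4.5e-07, adjusted p = 0.305 with an estimated correlation). Fatty acid uptake and oxidation had 6 lower and 1 higher of 29 after ORX in control (8 and 2, 0.00461, adjusted p = 0.377 with an estimated correlation), with a median of -0.282 that was 0.0231 with total counts. In mARKO 7 fell with SARM (7, 1.89e-06, adjusted p = 0.147 with an estimated correlation), and the SARM effect was more negative than in control for 11 genes (16, 2.38e-10, adjusted p = 0.0539 with an estimated correlation). Proteasome subunits had 4 of 31 higher after ORX in control (4, 0.000575, adjusted p = 0.58 with an estimated correlation) and 3 lower with SARM (7, 3.54e-06, adjusted p = 0.384 with an estimated correlation). In mARKO 5 fell with SARM (4, 0.000113, adjusted p = 0.317 with an estimated correlation). The integrated stress response had 8 lower and 1 higher of 20 after ORX in control (10 and 2, 0.00735, adjusted p = 0.275 with an estimated correlation) and 5 higher and 1 lower with SARM (7 and 2, 0.0159, adjusted p = 0.334 with an estimated correlation). In mARKO 10 of 19 rose and 2 fell with SARM (13 and 2, 0.000209, adjusted p = 0.253 with an estimated correlation). Unfolded protein and heat shock genes had 11 higher and 5 lower of 23 with SARM in mARKO (14 and 6, 0.00928, adjusted p = 0.305 with an estimated correlation). Interferon response genes had 6 of 24 higher there (7, 0.000383, adjusted p = 0.305 with an estimated correlation), with the epithelial marker level at 5.37 against 3.78 with vehicle. After ORX in mARKO the lists of interferon response (0.0282), unfolded protein and heat shock (0.0266) and fatty acid uptake (0.00532) were called with 0, 2 and 2 genes higher and 0, 0 and 6 lower (0, 3 and 2 and 0, 0 and 8, adjusted p = 0.318, 0.228 and 0.195 with an estimated correlation). There the epithelial marker level went from 0.988 to 3.78, and with it as a covariate, chosen after the result was seen, the interferon (0.677) and unfolded protein lists (0.111) lost their calls and turned to lower. Against sham, SARM-treated mARKO muscle had 19 of 29 fatty acid genes lower (21, 5.4e-10), 14 of 31 proteasome genes lower (15, 9.91e-06), 15 of 24 interferon genes higher (18 and 1 lower, 9.91e-06), 10 of 19 stress response genes higher and 1 lower (10 and 1, 0.000719), and 12 unfolded protein genes higher and 6 lower (13 and 6, 0.00184). The lowest adjusted p = 0.11 with an estimated correlation among these. The epithelial marker level was 5.37 there against 0.988 in sham, and with it as a covariate the stress response (0.828) lost its call and turned to lower, and the proteasome genes (0.628) to higher. There 1 glucocorticoid-responsive gene was higher and 5 lower (1 and 5, 0.0225, adjusted p = 0.593 with an estimated correlation). Between genotypes, the ORX effect was called for proteasome (4.5e-07, adjusted p = 0.333 with an estimated correlation), integrated stress (0.0062, 0.301) and unfolded protein genes (0.00317, 0.415), with 0, 1 and 2 genes more positive and 1, 1 and 0 more negative (0, 5 and 8 and 4, 1 and 0). With the epithelial marker level as a covariate, which went from 0.988 to 3.78 after ORX in mARKO and from 4.44 to 4.49 in control, the integrated stress (0.626) and unfolded protein calls (0.641) ended and turned to more negative. The SARM effect was called for glucocorticoid-responsive (0.0148, adjusted p = 0.442 with an estimated correlation) and interferon genes (0.0105, 0.442), with 1 and 0 genes called (4 and 0). Calls that ended without 1 library were glucocorticoid (control SARM 2, 0.0915, and for mARKO against sham sham 3, 0.12, and SARM 3, 0.115), immediate early (mARKO vehicle 3, 0.211, and SARM 3, 0.068) and integrated stress in control ORX (sham 3, 0.079) and the ORX difference (control sham 3, 0.0513). Others were interferon in mARKO ORX (sham 2, 0.184, and vehicle 1, 0.0624) and the SARM difference (control vehicle 4, 0.0507, control SARM 3, 0.0733, and mARKO SARM 2, 0.0508), and unfolded protein in mARKO ORX (sham 2, 0.0718, and vehicle 3, 0.205). The glucocorticoid SARM difference ended without control SARM 3 (0.0723) or mARKO vehicle 3 (0.113) or SARM 3 (0.106).

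Markers of other cell types moved in mARKO too, and counts adjusted over the list alone again open the parentheses. Fibro-adipogenic progenitor markers had 8 of 15 lower after ORX (9, 2.38e-06, adjusted p = 0.195 with an estimated correlation) and 6 higher with SARM (7, 0.00305, adjusted p = 0.345 with an estimated correlation). Tendon markers had 4 lower and 1 higher of 9 after ORX (4 and 1, 0.00295, adjusted p = 0.168 with an estimated correlation) and 2 higher with SARM (6, 0.0267, adjusted p = 0.305 with an estimated correlation). Endothelial markers had 2 of 15 lower after ORX (5, 0.00132, adjusted p = 0.195 with an estimated correlation). Adipocyte markers had 3 of 14 higher after ORX (3, 0.0383, adjusted p = 0.473 with an estimated correlation) and 4 lower with SARM (6, 0.000166, adjusted p = 0.305 with an estimated correlation). In control they had 1 higher after ORX (1, 0.0385, adjusted p = 0.632 with an estimated correlation) and 2 lower with SARM (4, 0.00297, adjusted p = 0.415 with an estimated correlation). Satellite cell and myogenic genes had 4 of 23 lower after ORX in mARKO (4, 0.0157, adjusted p = 0.195 with an estimated correlation), and 7 fell and 2 rose with SARM (7 and 2, 0.0282, adjusted p = 0.305 with an estimated correlation). Slow fibre contractile genes had 3 of 12 lower after ORX in mARKO (4, 0.00453, adjusted p = 0.168 with an estimated correlation). IGF and insulin signalling differed between genotypes after ORX, with 4 of 20 genes more negative in mARKO (4, 0.000833, adjusted p = 0.0576 with an estimated correlation). Ribosome biogenesis had 3 of 30 higher after ORX in control (3, 0.00735, adjusted p = 0.377 with an estimated correlation), and 1 lower with SARM in control (0, 0.0468, 0.489) and in mARKO (0, 0.0198, 0.305). After ORX in mARKO the IGF list had 4 higher and 6 lower (4 and 7, 0.0448, adjusted p = 0.228 with an estimated correlation). Against sham, SARM-treated mARKO muscle had lower pericyte (7 of 15, list alone 7, 0.000621), satellite cell (11 of 23, with 2 higher, list alone 12 and 2, 0.000166), denervation (8 of 20, with 1 higher, list alone 9 and 1, 0.00184) and slow fibre genes (8 of 12, with 1 higher, list alone 8 and 2, 0.00134), each with adjusted p = 0.11 with an estimated correlation. Endothelial markers had 4 lower and 1 higher (5 and 1, 0.0189, adjusted p = 0.311 with an estimated correlation) and extracellular matrix genes 8 lower and 1 higher (8 and 1, 0.00566, 0.538). With the epithelial marker level as a covariate the matrix call ended and turned to higher (0.398). In control the denervation list was not called after ORX (0.282) or with SARM (0.066), and against sham ribosomal proteins (0.00191) and oxidative phosphorylation (0.000576) were called with 0 genes (0 in each, adjusted p = 0.908 with an estimated correlation). The ORX difference was called for glycolysis (2.95e-06, adjusted p = 0.459 with an estimated correlation), oxidative phosphorylation (0.000211, 0.613), fast fibre (0.000833, 0.489), TCA cycle (0.00317, 0.501), pericyte (0.000253, 0.333), progenitor (0.00317, 0.483), macrophage (0.0163, 0.483), atrophy (0.0386, 0.489) and slow fibre genes (0.0386, 0.233). The control vehicle libraries stood apart in the pericyte markers, with a mean log2(CPM + 1) of 4.918 and 5.114 in replicates 1 and 2 and 6.319 and 6.236 in 3 and 4. The SARM difference was called for ribosomal proteins (1.09e-06, adjusted p = 0.538 with an estimated correlation), epithelial (3.06e-05, 0.35), macrophage (0.0022, 0.35) and satellite cell genes (0.0368, 0.35). Calls that ended without 1 library were adipocyte in control ORX (sham 3, 0.261, vehicle 2, 0.125, and vehicle 4, 0.0564), control SARM (SARM 2, 0.0599) and mARKO ORX (sham 2, 0.247, vehicle 1, 0.0531, and vehicle 2, 0.256), and IGF in mARKO ORX (sham 1, 0.146, sham 2, 0.077, and vehicle 1, 0.086). Ribosome biogenesis lost its call in control ORX (sham 1, 0.0813), control SARM (vehicle 1, 0.0753, vehicle 4, 0.0941, SARM 2, 0.0728, and SARM 3, 0.223) and mARKO SARM (vehicle 1, 0.0662). Satellite cell lost it in mARKO ORX (sham 2, 0.0718) and SARM (SARM 3, 0.068) and without 6 libraries in the SARM difference (0.0514 to 0.0842), tendon in mARKO SARM (vehicle 1, 0.0673, and SARM 1, 0.0629), and endothelial against sham (SARM 3, 0.0906). In the ORX difference the Schwann cell (0.0519 to 0.16), macrophage (0.0735 to 0.128), atrophy (0.0541 to 0.0985) and slow fibre calls (0.0557 to 0.101) ended without 6, 4, 7 and 5 libraries, and the progenitor call without control sham 3 (0.0775). In the control sham comparison ribosomal proteins lost it without sham 2 (0.0632) or SARM 1 (0.131) and oxidative phosphorylation without sham 2 (0.0662) or SARM 3 (0.0563). Cell cycle, circadian clock, polyamine metabolism, sterol and fatty acid synthesis, the myostatin and activin pathway, and histone and RNA quality markers were called in no comparison, nor were the neutrophil markers, tested in mARKO alone. Schwann cell and nerve markers were called only for the ORX difference between genotypes (0.0386, adjusted p = 0.459 with an estimated correlation, 0 of 12 genes called and 0 adjusted over the list alone).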
